A study of Gallus gallus with 12 samples.

How the data were processed

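RNA-seq libraries were labelled as hypothalamus or whole brain of White Leghorn chicken embryos on embryonic day 18. Per the labels, control eggs (CT) were incubated at 37.8 °C throughout, and eggs given embryonic thermal manipulation (ETM) were held at 39.5 °C from embryonic day 13 to day 18. The relative humidity of the incubator is 65% in the design text and 60% in the growth protocol. Each of the 4 groups (tissue by treatment) held 3 libraries, and every library carries the same batch label. Per the labels, total RNA was extracted with TRIzol and libraries were built with a Fast RNA-seq kit (V2). The sequencer was an Illumina NovaSeq X Plus. The design text calls the replicates biological, but the labels do not say whether a library held tissue of 1 embryo or of several, so p-values measure the spread between these libraries.

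The authors deposited a table of raw counts per gene, which per the submitters' processing notes were made with featureCounts of Subread 2.0.6 on the genome build GRCg7b. The authors also deposited a table of FPKM values, which are counts scaled to gene length and to the reads of the library, for the same genes and libraries. The aligner, the strand setting and the handling of reads that map to several genes are not given in the sources used here, so genes that overlap one another or have near-identical copies carry that uncertainty. Coordinates, gene lengths, biotypes and symbols are those of the deposited tables, on build GRCg7b. The count table had 30742 rows, of which 14248 carried a gene symbol, 17007 were protein coding and 11944 were long noncoding RNAs. A further 634 rows had no gene name, held 0.513% of all counts and were kept in the tests and library totals, except in the alternative of protein-coding genes alone. No genome sequence was used here, so GC content was not examined.

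In 11 of the 12 libraries the FPKM values were the counts divided by gene length and 1 constant per library, to within 0.1%. In treated hypothalamus library 1 they were not, and the count column was used for that library. Pairs of libraries of 1 group differed by more than counting noise, with chi-square values per degree of freedom from 5.462 to 34.65 over 12 pairs, so no library was counted as a duplicate.

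Before the data were examined, the following choices were fixed: the tests, the samples in each fit, 28 pathway lists and 20 cell type or region lists, the rule for the genes to name, and most of the alternatives. The deposited counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr and the quasi-likelihood test, and p-values were adjusted by the Benjamini-Hochberg method. A gene was called at an adjusted p below 0.05. Treatment was tested within each tissue on its own 6 libraries. The difference between the tissues in their response (interaction) and the difference between the tissues in control embryos were tested in 1 fit of all 12 libraries with 4 groups. Levels are CPM, the counts scaled to library size, after TMM scaling, as mean ± SD over 3 libraries. Fold changes are given on the log2 scale with a standard error (SE). The SE was derived from the quasi-likelihood F and the unshrunk fold change, while the fold change printed is the shrunken one of edgeR. The SE is thus approximate, most of all for genes with few counts. The CPM of a gene can differ slightly between the fit of 6 libraries and that of 12. In the figures, and for levels of NKX2-1 and GABRA6 in the closing section, TMM factors came from all genes before the count filter. A chromosome 16 row without a gene name (1639025 to 1642068) was scaled to library totals alone.

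Gene lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01 on log2 CPM, adjusted over the 48 lists within a comparison. The camera test was repeated with the correlation estimated for each list, and fry was run on the same lists. Of 1198 genes listed, 1023 symbols were found in the table. Members of a list were counted at adjusted p below 0.05 over all genes tested, and again adjusted over the list alone.

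Genes were named by a rule. For each comparison the rule took the 10 largest positive and 10 largest negative changes (5 and 5 for the interaction) among called genes with a symbol and a mean of at least 1 CPM, without overlap between the groups' libraries for all but the interaction. It added up to 4 members of each list with the lowest p, a fixed set of stress, temperature and regional genes, and, where fewer than 10 genes passed, the 10 symbols with the lowest p. CIRBP and AGRP of the fixed set were not found by symbol in the table, and POMC and TTR were too low to be tested in the hypothalamus. Outside this rule fell the unnamed chromosome 16 and chromosome 24 genes and the chromosome 16 row without a gene name. So did the comparison of larger chromosomes (1 to 10) with microchromosomes (11 to 39). All of these were chosen after their values were seen. Some genes that the rule names are not reported here.

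The alternatives were DESeq2 1.42.0, other scalings and count filters, protein-coding genes alone, Z- and W-linked genes left out, a covariate for W-linked genes, the replicate number as a block, other thresholds, limma on log2(FPKM + 1) and log2(FPKM + 0.1), 1 fit of all libraries, and each library left out in turn. Added after the data were seen were offsets for chromosome and gene length in each library, the libraries with a W-linked share of counts below 0.05% (a cut set after the shares were seen), chromosome 16 left out, and reads recovered from the FPKM column of treated hypothalamus library 1 in place of its counts. Those reads came out whole to within 0.01 for 99.95% of values and summed to 12161593. The limma fits on FPKM hold that differing column, so they are not a test of the same 12 libraries.

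Each test was first checked on simulated counts with 200 changed genes. Counts were drawn independently for each gene, without a tissue difference or a trend with chromosome. The shares recovered need not hold for these data, least of all for the whole brain, where far more genes were called. In the hypothalamus comparison, with 15405 genes, 16.4% of changes of 1.5-fold, 52.2% of 2-fold and 89.4% of 4-fold were recovered, and 12 of 117 calls were false. In the whole brain comparison, with 15305 genes, these shares were 49.3%, 71.6% and 90.9%, with 8 of 149 calls false. For the interaction over 16201 genes they were 2.99%, 38.8% and 72.7% with 3 of 79 calls false, and for the control comparison of the tissues over 16201 genes they were 22.4%, 56.7% and 87.9% with 6 of 117 calls false. Within a tissue the 6 libraries allow 10 splits into 3 and 3, so no count of splits can fall below a share of 0.1.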

Results

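Gene expression was measured by RNA-seq in 12 libraries from chicken embryos on embryonic day 18. By label there were 4 groups of 3: control (CT) and heat-exposed (ETM, embryonic thermal manipulation) hypothalamus, and control and heat-exposed whole brain. Total counts ranged from 13309467 to 18317019 per library. Tissue separated the libraries along the first principal component, which held 53.6% of the variance of log2 CPM. Correlations of log2 CPM ran from 0.971 to 0.98 among control and from 0.965 to 0.974 among treated hypothalamus libraries, from 0.984 to 0.986 among control and from 0.975 to 0.987 among treated whole brain libraries, and from 0.895 to 0.944 between tissues. Counts from genes of the W chromosome, which female birds carry, made up 0.1196% of control hypothalamus library 3 (95% Wilson interval 0.1179 to 0.1214), 0.1129% of treated hypothalamus library 2 (0.1112 to 0.1146) and 0.1472% of treated whole brain library 1 (0.1454 to 0.1491). These intervals cover counting error only. In the other 9 libraries they lay between 0.0105% and 0.0174%.

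The control libraries of the tissues were compared to see which regional genes each label holds. Genes of the pallium and choroid plexus were lower in the libraries labelled hypothalamus. TBR1, of pallial glutamatergic neurons (ENSGALG00010021076, chromosome 7, 20991498 to 20996892, build GRCg7b), measured 0.0363 ± 0.0628 CPM there and 148 ± 29.2 CPM in whole brain (SD, n = 3 each). TTR, the thyroid hormone carrier made by the choroid plexus, measured 0.346 ± 0.174 and 936 ± 221 CPM. Of genes of serotonin neurons, SLC6A4 and TPH2 were higher in the libraries labelled hypothalamus. The serotonin transporter SLC6A4 differed by 4.54 ± 0.79 on the log2 scale (SE, with 379.7 ± 81.8 against 16.3 ± 8.8 CPM). TPH2, which makes serotonin, differed by 3.96 ± 0.71 (183 ± 47.2 against 11.8 ± 5.58 CPM). The fixed monoamine signalling list had 16 members higher and 9 lower of 32. It did not pass camera (adjusted p = 0.0743) and passed fry (adjusted p = 0.0173).

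Among transcription factors of the midbrain and hindbrain, FOXA2 was higher by 5.05 ± 0.41 (14.6 ± 1.05 against 0.43 ± 0.176 CPM), EN1 by 2.85 ± 0.30 (58.6 ± 7.25 against 8.15 ± 1.31 CPM), PAX5 by 4.66 ± 0.71 and EN2 by 1.28 ± 0.18. Of hypothalamic regulators, OTP was higher by 2.02 ± 0.50 and HMX3 by 1.72 ± 0.56, and SIM1 by 0.92 ± 0.30. OTP measured 43.08, 6.204 and 20.6 CPM in the control hypothalamus libraries and 5.323 to 6.103 CPM in whole brain controls. Without control hypothalamus library 1 its difference was 1.22 (edgeR adjusted p = 0.0407), and it lost the call in 3 of 27 alternatives (highest adjusted p = 0.132). Calls were lost in 7 of 28 alternatives for HMX3 and 9 of 26 for SIM1. The HMX3 call was lost without control hypothalamus library 1 (edgeR adjusted p = 0.128) or without whole brain control library 1 (0.095), 2 (0.0577) or 3 (0.0757), and the SIM1 call without control hypothalamus library 2 (0.0721) or 3 (0.104) or whole brain control library 1 (0.07), 2 (0.0775) or 3 (0.0872). NKX2-1, a regulator of the ventral hypothalamus (ENSGALG00010004654, chromosome 5, 36138043 to 36144905), was lower in the libraries labelled hypothalamus, at 0.0459 ± 0.0795 against 5.62 ± 0.844 CPM. POMC was lower by −4.94 ± 0.94 and AVP by −2.90 ± 0.17 on the log2 scale, and TRH did not pass the test at −0.67 ± 0.50 (edgeR with Benjamini-Hochberg adjustment, adjusted p = 0.322). GABRA6 of cerebellar granule cells measured 0.341 ± 0.203 against 10.7 ± 1.37 CPM.

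**Figure D1:**
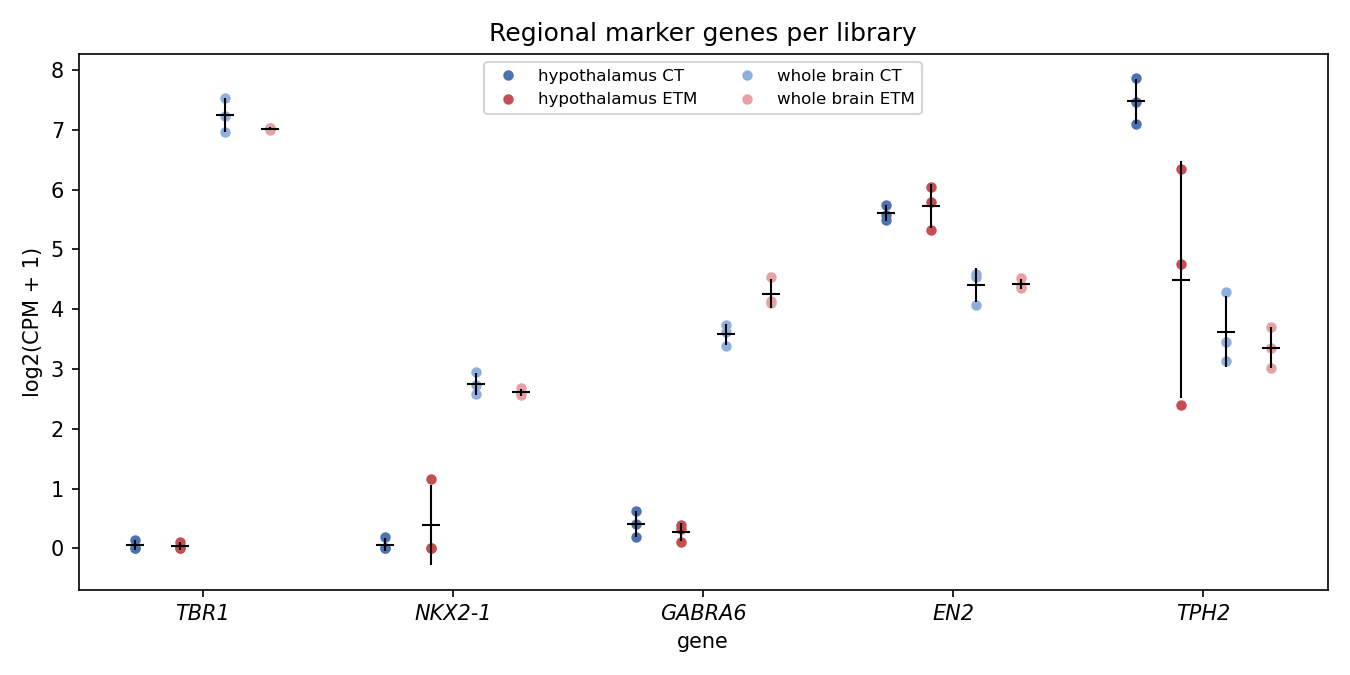
Levels of 5 regional marker genes in each of the 12 libraries, as log2(CPM + 1). Dots are libraries, colours are the 4 groups, and black bars are the mean ± SD of 3 libraries. TBR1 and GABRA6 are near 0 in both groups labelled hypothalamus, and TPH2 is high in the control libraries of that label and spreads widely in the treated ones.

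In all, 5564 of 16201 genes passed the edgeR quasi-likelihood test between the tissues, 2710 higher and 2854 lower in the libraries labelled hypothalamus, and 1860 of these differed by at least 1 on the log2 scale. Of 16201 genes, 7983 (49.3%) had no overlap between the 3 and 3 libraries, where chance gives 10%. Of the 48 lists, 17 passed camera, 7 higher and 10 lower. Of the pallium list, 13 of 19 members were lower and 0 higher (also 14 lower adjusted over the list alone; camera adjusted p = 6.02e-41), among them NEUROD6 by −4.29 ± 0.15. The striatum list had 9 lower and 3 higher of 18 (9 and 3 adjusted over the list alone), with PPP1R1B, a marker of striatal projection neurons, at −5.04 ± 0.20. The immediate-early list had 12 lower and 2 higher of 20 (13 and 2 adjusted over the list alone), with EGR3 at −4.33 ± 0.23, and the choroid plexus list had 10 lower and 2 higher of 19 (10 and 3 adjusted over the list alone). These 4 lists held with an estimated correlation (adjusted p = 0.000746 for pallium, 0.0199 for striatum, 0.0243 for immediate-early genes and 0.0243 for choroid plexus).

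Myelin genes were higher in the libraries labelled hypothalamus, 17 of 20 with 1 lower (the same counts adjusted over the list alone), including UGT8 by 2.04 ± 0.19 and NKX6-2 by 2.12 ± 0.14. The camera adjusted p was 4.24e-12, and the call was lost with an estimated correlation (adjusted p = 0.158 with an estimated correlation). The midbrain and optic tectum list had 10 higher and 5 lower of 21 members (10 and 6 adjusted over the list alone; adjusted p = 0.0177, and adjusted p = 0.578 with an estimated correlation); without whole brain control library 2 it did not pass (adjusted p = 0.0611). The list of hypothalamic transcription factors had 8 higher and 10 lower of 28 (10 and 12 adjusted over the list alone) and did not pass camera, adjusted p = 0.341.

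The next comparison asked what heat exposure changed in the libraries labelled hypothalamus. Heat shock genes were among the few that passed. HSPA2, a 70-kDa-family chaperone (ENSGALG00010017470, chromosome 5, 52384531 to 52387031), rose by 1.25 ± 0.13 on the log2 scale, from 124 ± 2.06 to 294 ± 42.7 CPM (SD, n = 3 each; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.0311). The small heat shock gene HSPB9 (ENSGALG00010023206, chromosome 27, 4832280 to 4835756) rose by 1.25 ± 0.15, from 10.6 ± 0.624 to 25.2 ± 2.39 CPM (edgeR adjusted p = 0.0332). HSP90AB1, the constitutive HSP90 gene (ENSGALG00010019591, chromosome 3, 29961061 to 29967272), fell by 1.46 ± 0.19, from 224 ± 44.8 to 81.7 ± 19.5 CPM (edgeR adjusted p = 0.0458). B3GNT3, a glycosyltransferase gene (ENSGALG00010027611, chromosome 28, 3767716 to 3770759), rose by 2.09 ± 0.27, from 1.28 ± 0.082 to 5.49 ± 0.42 CPM (edgeR adjusted p = 0.0441). The control and treated libraries did not overlap for any of these 4 genes.

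Only 7 of 15405 genes passed the edgeR quasi-likelihood test, 6 higher and 1 lower (6 and 0 with RLE scaling, where HSP90AB1 had an adjusted p of 0.0527), and 1594 had an unadjusted p below 0.05 where 770 are expected by chance. The remaining 3 were unnamed protein-coding genes, singled out after their values were seen. ENSGALG00010002366 (chromosome 16, 1622270 to 1634221) and ENSGALG00010002378 (chromosome 16, 1631899 to 1635728) overlap each other and each rose by 2.47 ± 0.28, and ENSGALG00010024511 on chromosome 24 rose by 0.92 ± 0.11. The 5.8S ribosomal RNA gene lies within the first of the chromosome 16 genes, so reads of the ribosomal repeat cannot be separated from theirs. With chromosome 16 left out, edgeR called 1 gene, 1 higher and 0 lower, and 1 of the 7 calls was kept. Most calls on other chromosomes, HSP90AB1 among them, thus passed only with the chromosome 16 genes in the test. No overlap between groups was found for 2489 genes (16.2%), where chance gives 10%. Of genes that did not pass, DNAJC12 measured −1.05 ± 0.15 (edgeR adjusted p = 0.0571), MYOC 0.91 ± 0.13, AGT 0.82 ± 0.12, BAG3 0.98 ± 0.15 (adjusted p = 0.0718), HERC3 −0.77 ± 0.13 and RDH8 1.27 ± 0.21. Of 24 alternatives, DNAJC12 passed in 8, MYOC and AGT in 7, BAG3 in 5, HERC3 in 4 and RDH8 in 3. The 24 include the main fit read at adjusted p below 0.1. DNAJC12, BAG3, MYOC (edgeR adjusted p = 0.0571) and AGT (0.0603) passed there by their main values alone. Corticotropin-releasing hormone (CRH) measured −1.16 ± 0.31 (edgeR adjusted p = 0.256), HSP90AA1 0.54 ± 0.15, HSPH1 0.53 ± 0.14 and RBM3 0.55 ± 0.15, and none passed, although CRH, HSP90AA1 and RBM3 each passed in 1 alternative. Nor did HSPA8 (0.20), HSPA5 (0.02), TRH (0.01), AVP (0.53), NPY (−0.52), DIO2 (−0.43), FKBP5 (0.31), BDNF (0.05), FOS (−0.10), MBP (0.38) or HBA1 (−0.67).

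**Figure D2:**
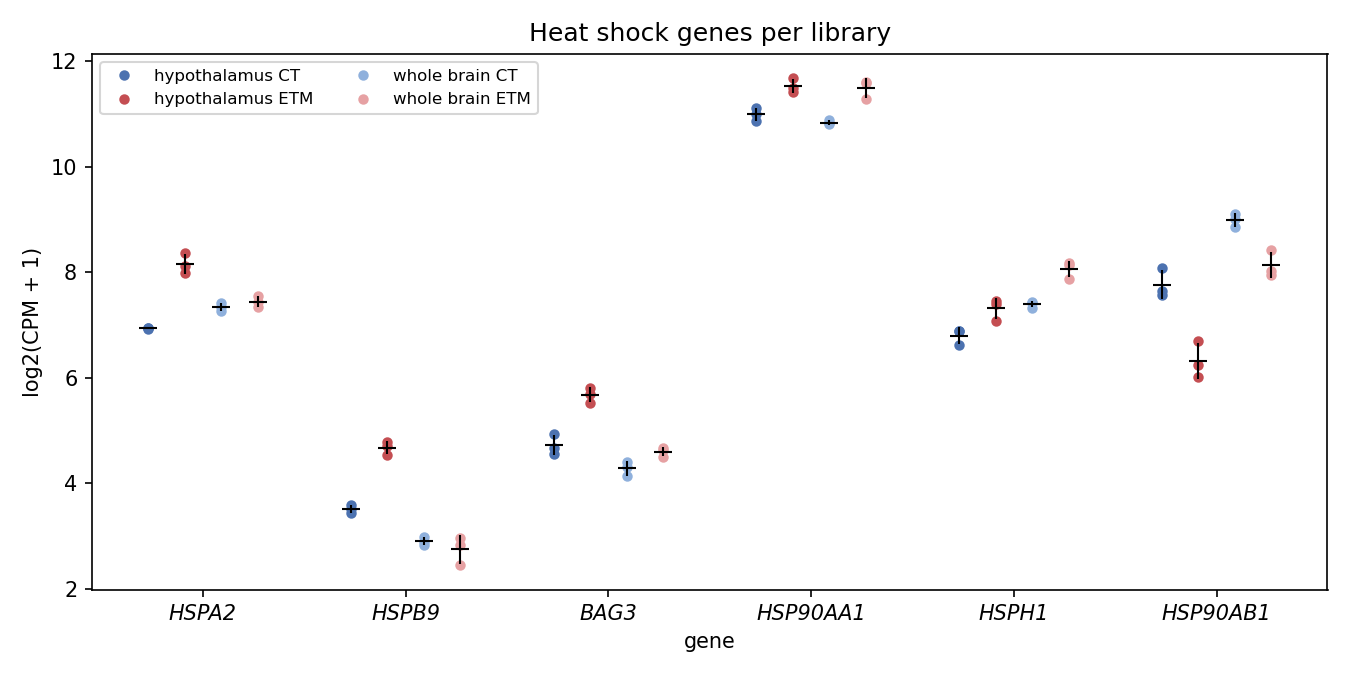
Levels of 6 heat shock genes in each of the 12 libraries, as log2(CPM + 1). Dots are libraries, colours are the 4 groups, and black bars are the mean ± SD of 3 libraries. HSPA2 and HSPB9 separate treated from control libraries labelled hypothalamus, and HSP90AB1 is lower with heat exposure under both tissue labels.

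The 8 list calls in this paragraph are those of camera at its preset correlation, and each was lost at adjusted p = 0.682 with an estimated correlation. Of 37 heat shock and co-chaperone genes tested, 2 rose and 1 fell, and 13 rose and 1 fell adjusted over the list alone (camera adjusted p = 9.68e-09, higher). The ependyma and cilia list was higher (adjusted p = 8.3e-07), with 0 of 27 members passing and 4 adjusted over the list alone; DNAI2 measured 0.80 ± 0.18. Lists with lower values were proliferation (adjusted p = 1.12e-06, 0 of 30 passing, RRM1 at −0.63 ± 0.12), monoamine signalling (adjusted p = 1.25e-05, 0 of 32 passing), cholesterol synthesis (adjusted p = 0.00217, 0 of 22 passing, HMGCS1 at −0.59 ± 0.14), endothelium (adjusted p = 0.00621, 0 of 18 passing, VWF at −0.49 ± 0.12) and red blood cells (adjusted p = 0.00877, 0 of 13 passing, TFRC at −0.53 ± 0.13). Adjusted over the list alone, these had 1, 0, 1, 1 and 2 members lower. The myelin list was higher (adjusted p = 0.000327, 0 of 20 passing and 1, TMEM88B at 0.93 ± 0.17, adjusted over the list alone). The fry test called 0 lists, its lowest adjusted p being 0.464. The myelin list did not pass without control library 1 (camera adjusted p = 0.0746) or treated library 1 (0.0688), endothelium without control library 3 (0.116), and cholesterol synthesis (0.204) and red blood cells (0.0572) without treated library 3.

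Within the monoamine list, TPH2 measured −2.32 ± 0.71 and DDC −1.49 ± 0.46 without passing. TPH2 ranged from 140.1 to 235.9 CPM in the control libraries and stood at 81.42, 4.351 and 27.02 CPM in the treated ones. Each treated library thus held less of this serotonin gene than any control library, by amounts that differed widely.

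The number of hypothalamus calls moved when single libraries were left out, while the fold changes of the 4 genes with a symbol kept their sign. Those 4 genes were named for having no overlap between the groups, so a kept sign was likely and says little. Over 24 alternatives the log2 fold change ran from 1.126 to 1.396 for HSPA2 and from 1.124 to 1.365 for HSPB9. For HSP90AB1 it ran from −1.661 to −1.283 and for B3GNT3 from 1.372 to 2.581. Leaving out any control library or treated library 3 left 0 genes with edgeR (1169 to 1325 at an unadjusted p below 0.05), leaving out treated library 1 gave 39, leaving out treated library 2 gave 4, and DESeq2 on all 6 libraries called 187. Counts and FPKM of treated library 1 hold different reads; with the reads recovered from FPKM edgeR called 0 genes (1423 at an unadjusted p below 0.05), and the heat shock list was higher at the preset correlation of camera (adjusted p = 0.00158). From the counts that list had adjusted p = 0.682 with an estimated correlation, which was not run on the recovered reads.

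In the whole brain, heat exposure went with a broad difference. AVP, the precursor of the antidiuretic hormone vasotocin in birds (ENSGALG00010016587, chromosome 4, 88244481 to 88246114), fell by 1.15 ± 0.08 on the log2 scale. Its level went from 63.7 ± 1.19 to 28.8 ± 0.904 CPM (SD, n = 3 each, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 3.81e-05). Of 24 hypothalamic transcription factors 8 fell and 0 rose, and 0 had a positive fold change. That list passed fry (adjusted p = 0.00883) but not camera (adjusted p = 0.0559, and 0.665 with an estimated correlation). Of 28 hypothalamic neuropeptide genes, AVP among them, 5 rose and 5 fell. The type I collagen gene COL1A1 (ENSGALG00010025092, chromosome 27, 2738241 to 2755487) fell by 1.90 ± 0.12, from 652 ± 44.1 to 174 ± 28.8 CPM (edgeR adjusted p = 2.63e-05), and COL1A2 fell by 1.34 ± 0.09. The mitochondrial gene ND6 (ENSGALG00010000037, 14962 to 15483 of the mitochondrial genome) rose by 2.02 ± 0.18, from 132 ± 11.9 to 534 ± 150 CPM (edgeR adjusted p = 7.64e-05). Chaperone genes moved both ways: HSP90AA1 rose by 0.68 ± 0.09 (1780 ± 62.6 to 2843 ± 361 CPM), HSPH1 rose by 0.68 ± 0.09, and HSP90AB1 fell by 0.84 ± 0.12 (496 ± 40.3 to 278 ± 49.6 CPM).

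The 10 largest increases by the naming rule ran from 1.53 to 2.44 on the log2 scale: MMRN1 2.44 ± 0.37, IGSF1 2.19 ± 0.46, SPDYA 2.06 ± 0.44, ND6, PLD4 1.70 ± 0.50, OTOS 1.64 ± 0.29, TNFSF15 1.61 ± 0.36, C4orf45 1.58 ± 0.42, C8orf88 1.54 ± 0.41 and MAT1A 1.53 ± 0.40. Apart from ND6, OTOS and TNFSF15, their treated means stayed below 3 CPM. PLD4 lost the call without control library 1 (edgeR adjusted p = 0.0561) or treated library 2 (0.092), and C8orf88 without treated library 2 (0.0516). The 10 largest decreases by the same rule included PFDN2, a prefoldin subunit (ENSGALG00010028030, chromosome 25, 2861684 to 2863468), at −5.45 ± 0.48 (33.1 ± 17.3 to 0.738 ± 0.561 CPM), the 5_8S_rRNA gene (ENSGALG00010003618, chromosome 16, 1629398 to 1629550) at −4.00 ± 0.57, CCDC69 at −4.15 ± 0.36, LIN28A at −4.20 ± 0.61, FSCN2 at −3.21 ± 0.50, DCST2 at −3.01 ± 0.53 and MFRP at −2.43 ± 0.33. Another 3 lie side by side on chromosome 34, from 2234361 to 2271735: GALNT6 at −3.27 ± 0.21 (10.6 ± 0.838 to 1.09 ± 0.175 CPM), CELA1 at −5.85 ± 0.58 and BIN2 at −2.68 ± 0.31. The 5_8S_rRNA gene fell along with ENSGALG00010002366 (−4.39), the gene it lies within. For ribosomal RNA reads, a preparation difference that follows the groups cannot be told apart from heat exposure.

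Of the fixed genes, RBM3 rose by 0.42 ± 0.07, BDNF by 0.49 ± 0.17 (edgeR adjusted p = 0.0391) and TTR by 0.52 ± 0.18 (adjusted p = 0.0357), while FOS fell by 0.55 ± 0.15 and the haemoglobin gene HBA1 fell by 1.11 ± 0.29. FOS and HBA1 each lost the call in 2 of 23 alternatives (highest edgeR, DESeq2 or limma adjusted p = 0.0592 and 0.0524), BDNF in 10 and TTR in 9. BDNF lost it without control library 2 (edgeR adjusted p = 0.132) or 3 (0.0913) or treated library 1 (0.14) or 2 (0.0616), and TTR without control library 2 (0.0999) or treated library 1 (0.129) or 2 (0.0616). HSPA2 (0.11 ± 0.08, edgeR adjusted p = 0.32), HSPA8 (0.11), HSPA5 (0.10), CRH (−0.16), TRH (−0.25), POMC (−0.22), NPY (−0.07), DIO2 (0.08), FKBP5 (−0.06) and MBP (0.25) did not pass. With the offsets for chromosome and gene length, 1 of 23 alternatives, HSPA8 measured 0.40 (edgeR adjusted p = 0.000762) and HSPA5 0.31 (0.0035).

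In all, 6787 of 15305 genes passed (44.3%), 3230 higher and 3557 lower, and 797 of these changed by at least 1 on the log2 scale, 265 higher and 532 lower. The median size of the changes called was 0.575. No overlap between the groups was found for 8562 genes (55.9%), where chance gives 10%. The called genes were unevenly spread over the chromosomes. On chromosomes 1 to 10, 28.8% of 7790 protein-coding genes rose and 16.1% fell, with a median log2 fold change of 0.129. On the microchromosomes, the small gene-dense chromosomes 11 to 39, 11.8% of 4843 protein-coding genes rose and 41% fell, with a median of −0.264. Microchromosomal genes took 43.86% to 46.32% of autosomal protein-coding counts in the 3 control libraries and 38.95% to 40.16% in the 3 treated ones. In the hypothalamus comparison the medians of these classes were −0.0168 and 0.044.

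**Figure D3:**
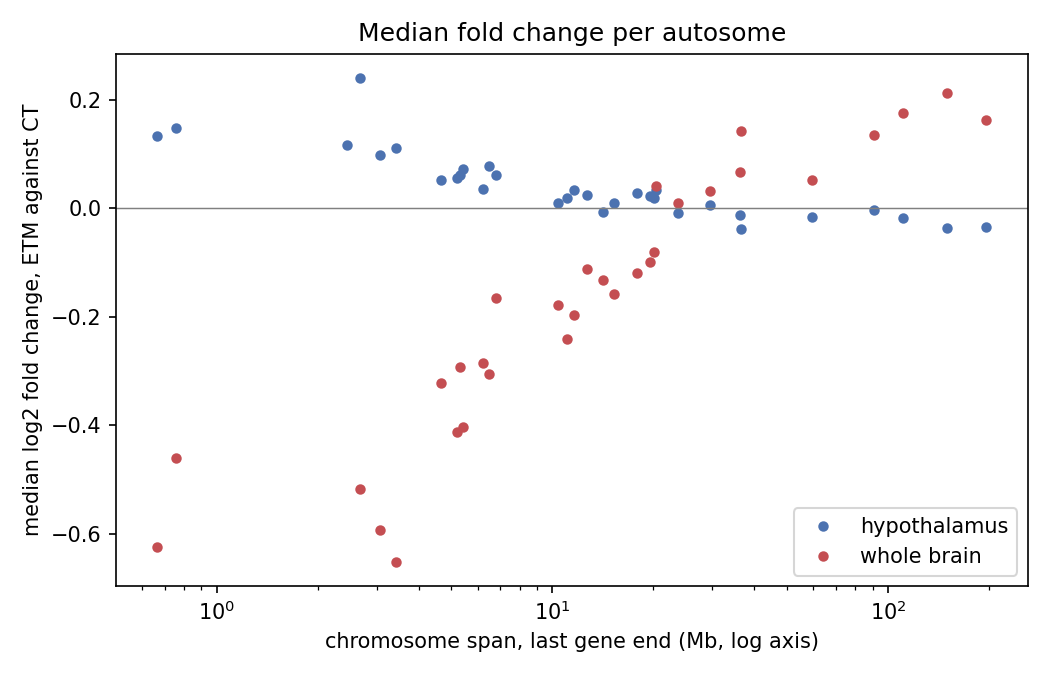
Median log2 fold change of ETM against CT for the tested protein-coding genes of each autosome with at least 20 of them, against the position of its last gene in Mb on a log axis. Each dot is 1 chromosome, in blue for the libraries labelled hypothalamus and in red for whole brain. Whole brain medians run from −0.652 on chromosome 34 to 0.212 on chromosome 2.

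Several pathway groups were higher with camera at its preset correlation, and each of these calls was lost at adjusted p = 0.665 with an estimated correlation. Of 13 mitochondrially encoded genes, 11 rose and 0 fell (12 adjusted over the list alone; camera adjusted p = 9.36e-05), with ND2 at 0.61 ± 0.07. The mitochondrial share of counts was 6.165% to 6.291% in the 3 control and 7.092% to 8.616% in the 3 treated libraries. GABA signalling genes were higher, 11 rising and 2 falling of 23 (the same adjusted over the list alone; adjusted p = 0.00596), with the receptor subunit GABRB2 at 0.74 ± 0.09 and the chloride transporter SLC12A5 at −0.52 ± 0.08. Of 37 heat shock and co-chaperone genes 16 rose and 5 fell (17 and 5 adjusted over the list alone; adjusted p = 0.0309), with CACYBP at 0.75 ± 0.09. Of 26 endoplasmic reticulum folding genes 10 rose and 1 fell (the same adjusted over the list alone; adjusted p = 0.0434), with the chaperone HSP90B1 at 0.73 ± 0.07 and DNAJB9 at 1.05 ± 0.16. Of 11 cold-inducible and temperature-responsive RNA-binding genes 7 rose and 1 fell (the same adjusted over the list alone; adjusted p = 0.0457), with the splicing kinase CLK4 at 0.87 ± 0.10 and SRSF2 at −0.64 ± 0.08. The folding list did not pass without control library 1 (camera adjusted p = 0.0537) or 3 (0.103) or treated library 1 (0.0687), the cold-inducible list without control library 1 (0.0702) or 3 (0.0822) or treated library 1 (0.0572) or 3 (0.0989), and the heat shock list without treated library 1 (0.0572).

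Markers of several cell types and glycolysis genes were lower with camera at its preset correlation, and these calls were lost at adjusted p = 0.67 for myelin and adjusted p = 0.665 for the others with an estimated correlation. Of 18 genes of meninges and fibroblasts 11 fell and 3 rose (the same adjusted over the list alone; adjusted p = 0.00212). Of 19 myelin genes 8 fell and 1 rose (9 and 1 adjusted over the list alone; adjusted p = 0.028), with OLIG2 at −1.01 ± 0.08 and CLDN11 at −1.13 ± 0.13. Oligodendrocyte precursor genes had 5 of 10 lower and 0 higher (the same adjusted over the list alone; adjusted p = 0.0434), with CSPG4 at −0.89 ± 0.10; OLIG2 is in both of these lists. Red blood cell genes had 5 of 13 lower and 0 higher (the same adjusted over the list alone; adjusted p = 0.0434), with SPTB at −0.91 ± 0.10. Glycolysis genes had 11 of 21 lower and 1 higher (12 and 1 adjusted over the list alone; adjusted p = 0.028), with PFKL at −0.98 ± 0.09 and GAPDH at −0.53 ± 0.07. The precursor list did not pass without control library 3 (camera adjusted p = 0.0583) or treated library 1 (0.0572) or 3 (0.0696), red blood cells without control library 1 (0.0551) or 3 (0.0807) or treated library 1 (0.0687), and myelin without treated library 3 (0.0564). The fry test called 25 of 48 lists in the whole brain.

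Whether the response differed between the tissues was tested as the change in the libraries labelled hypothalamus minus the change in whole brain. Among called genes with a symbol that met the naming rule, positive differences were largest for the 5_8S_rRNA gene (6.47 ± 0.93), PFDN2 (5.21 ± 1.25), GALNT6 (4.33 ± 0.69), CCDC69 (4.12 ± 0.63) and MFRP (3.60 ± 0.51). Negative ones among the same genes were largest for MMRN1 (−4.21 ± 0.69), LCT (−3.11 ± 0.64), the vesicular glutamate transporter SLC17A8 (−2.79 ± 0.71), COL9A1 (−2.66 ± 0.56) and IGSF1 (−2.52 ± 0.73; edgeR adjusted p = 0.0248). PFDN2 measured 26.93, 20.79 and 0.3801 CPM in the treated libraries labelled hypothalamus, so its difference rests on libraries that disagree. Several others were near the floor in libraries of that label. The controls measured 0.1455 to 0.4822 CPM for 5_8S_rRNA and 0.4366 to 1.033 for CCDC69. The treated libraries measured 0.1245 to 0.3254 CPM for MMRN1 and 0.08135 to 0.1867 for LCT. For the 5_8S_rRNA gene, a preparation difference that follows the whole brain groups cannot be told apart from heat exposure. PFDN2 lost the call in 4 of 27 alternatives (highest adjusted p = 0.379), SLC17A8 in 4 of 27 (0.099), LCT in 1 of 25 (0.0636) and IGSF1 in 8 of 27 (0.0722). In all, 3917 of 16201 genes passed the edgeR quasi-likelihood test, 1926 with a positive and 1991 with a negative difference. Without whole brain control library 2, 2340 passed, and without treated whole brain library 2, 2492. The calls were unevenly spread over the chromosomes. On the microchromosomes, 22.4% of 5015 protein-coding genes passed with a positive and 6.72% with a negative difference. On the larger chromosomes these shares were 8.32% and 18.2% of 7981. With the offsets for chromosome and gene length, 2389 of the 3917 were kept in the same direction. With the reads recovered from FPKM, 2525 were kept. IGSF1 lost the call without control hypothalamus library 2 (edgeR adjusted p = 0.056) or 3 (0.0567), treated hypothalamus library 1 (0.0502), whole brain control library 1 (0.0517) or 3 (0.0602), or treated whole brain library 1 (0.0505) or 2 (0.0604).

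The 6 list calls in this paragraph are those of camera at its preset correlation, and each was lost at adjusted p = 0.895 with an estimated correlation. Myelin genes differed between the tissues, 8 of 20 positive and 0 negative (9 and 1 adjusted over the list alone; camera adjusted p = 0.000707), with OLIG2 at 1.25 ± 0.16. GABA signalling had 7 of 23 negative and 0 positive (9 and 0 adjusted over the list alone; adjusted p = 0.0028). Meningeal and fibroblast genes had 9 of 18 positive and 0 negative (10 and 1 adjusted over the list alone; adjusted p = 0.00998), with COL1A1 at 1.54 ± 0.23. Cilia genes had 7 of 27 positive and 0 negative (8 and 0 adjusted over the list alone; adjusted p = 0.0185), with DNAI2 at 1.29 ± 0.24. Mitochondrially encoded genes had 1 of 13 negative, ND6 at −2.30 ± 0.24 (1 adjusted over the list alone; adjusted p = 0.0191), and clock genes had 7 of 19 negative and 2 positive (the same adjusted over the list alone; adjusted p = 0.0455), with ARNTL2 at −1.23 ± 0.19 and PER2 at −0.87 ± 0.22. These genes each lost the call in 1 of 27 alternatives (limma adjusted p = 0.0518 and 0.0764). The fry test called 6 lists, with GABA signalling (adjusted p = 0.0375) and the clock (0.0315) among them and not myelin (0.104), meninges (0.104), cilia (0.227) or the mitochondrial list (0.213). The meningeal list did not pass without treated hypothalamus library 3 (camera adjusted p = 0.109). The cilia list did not pass without control hypothalamus library 1 (0.0533), treated hypothalamus library 2 (0.232) or 3 (0.109) or whole brain control library 1 (0.0616), and the mitochondrial list without control hypothalamus library 2 (0.0795), treated hypothalamus library 2 (0.232) or whole brain control library 1 (0.0555). The clock list did not pass without control hypothalamus library 2 (0.0795) or 3 (0.0669), treated hypothalamus library 2 (0.0752) or 3 (0.109), whole brain control library 1 (0.0596) or 3 (0.0708) or treated whole brain library 2 (0.0788).

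Of 14769 genes tested in both tissues, 3 were called in both. HSP90AB1 fell in both, where 0.237 genes lower in both are expected of independent lists, and 0 genes rose in both, where 1.29 are expected. The chromosome 16 genes ENSGALG00010002366 and ENSGALG00010002378 rose in the hypothalamus comparison and fell in whole brain, by 4.39 ± 0.39 and 3.91 ± 0.31. Across genes, which are not independent replicates, the log2 fold changes of the tissues had a Spearman correlation of −0.102 and a Pearson correlation of −0.0474.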

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

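Chosen after the result was seen were the tests of library trends, of a preparation difference, of regional marker genes and of the FPKM column. The interaction, list and split tests were planned, and the test of sex was added after the data were seen, with its bound written before its result. An edgeR interaction test found 3917 genes whose response differed between the tissues. Among 100 splits of the libraries drawn, 3 gave as many, with 4691 the highest of the others. Of the 99 other splits, 11 kept the real whole brain groups and called 330 to 4691 genes with a median of 1922, and 88 with regrouped whole brain libraries called at most 2. The count thus follows the whole brain difference, and the share of 3 in 100 does not exclude chance among the hypothalamus libraries. With the offsets for chromosome and gene length, 2389 of the 3917 genes were kept in the same direction. Among called genes with a symbol that met the naming rule, the largest differences, hypothalamus minus whole brain on the log2 scale, were 6.469 (5_8S_rRNA), 5.205 (PFDN2), 4.333 (GALNT6), 4.12 (CCDC69) and 3.596 (MFRP), and −4.212 (MMRN1), −3.107 (LCT), −2.792 (SLC17A8), −2.662 (COL9A1) and −2.524 (IGSF1). The lists that differed were myelin (camera adjusted p = 0.000707), GABA signalling (0.0028), meninges (0.00998), cilia (0.0185), mitochondrially encoded genes (0.0191) and the clock (0.0455), all at adjusted p = 0.895 with an estimated correlation. For the 6 lists, 59 of 100 splits gave as many and the highest other gave 16, so chance is not excluded. For the rank correlation between the tissues of −0.102, 75 of 100 splits lay as far from 0, the highest other at 0.484, so chance is not excluded here either.

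The first pattern weighed is the broad whole brain difference, 6787 genes with edgeR. Offsets that removed each library's trends with chromosome and gene length called 6145 genes, and 4913 of the 6787 were kept in the same direction, which argues against those trends as the whole cause. The offsets leave other differences between genes of 1 chromosome in place, and GC content was not examined. Without treated library 1, the only whole brain library with a W-linked share above 0.05%, 5701 were kept, which argues against the sex of the embryos. A chromosome 16 row without a gene name (1639025 to 1642068) measured at least 389.7 CPM in each control library and at most 10.2 in each treated one. What this row encodes was not tested. The 5_8S_rRNA gene, on the same chromosome, measured 7.979 to 37.39 CPM in the control libraries and 0.5191 to 2.231 in the treated ones. A preparation difference that follows the groups cannot be told apart from heat exposure, because each group holds a single treatment. Heat exposure itself stays open.

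Within the whole brain 1 of 10 splits gave as many genes (6787, highest other 1) and 2 of 10 as many lists (10, highest other 10). In the hypothalamus 1 of 10 gave as many genes (7, highest other 3) and 5 of 10 as many lists (8, highest other 17). Between the control tissues 1 of 10 gave as many genes (5564, highest other 0) and 1 of 10 as many lists (17, highest other 14). Splits of 3 against 3 are too few for a share under 0.05.

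The second pattern is the regional marker genes of the libraries labelled hypothalamus. Tissue made mainly of hypothalamus cannot be told apart from a mixture with other regions by these genes, because hypothalamic genes went both ways. NKX2-1 reached at most 0.136 CPM in controls labelled hypothalamus, against at least 4.99 in whole brain controls. VAX1, also a listed hypothalamic factor, was lower in each of 28 alternatives (log2 fold changes −8.541 to −1.903). OTP (2.02), HMX3 (1.72) and SIM1 (0.92) were higher, but lost the call in 3 of 27, 7 of 28 and 9 of 26 alternatives. Of 28 hypothalamic transcription factors 8 were higher and 10 lower (camera adjusted p = 0.341). Of 29 hypothalamic neuropeptide genes 5 were higher and 11 lower (camera adjusted p = 0.0839). Among the lower ones, POMC and AVP each kept the call in 28 of 28 alternatives. GABRA6 was at least 9.44 CPM in whole brain controls and at most 0.543 in controls labelled hypothalamus, which argues against exchanged labels. A candidate explanation is midbrain and rostral hindbrain tissue in these libraries: the midbrain list was higher (camera adjusted p = 0.0177), but not with an estimated correlation (adjusted p = 0.578). The hindbrain and medulla list had 6 higher and 3 lower of 9 members. It did not pass camera (adjusted p = 0.304) and passed fry (adjusted p = 0.0253).

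The third pattern is treated hypothalamus library 1, whose FPKM column, not used in the main comparisons, holds a signal above that of the counts: W-linked genes made up 0.0986% of its recovered reads (95% Wilson interval 0.09683 to 0.1004) and 0.0105% of its counts (0.009947 to 0.01105). In this library 2999 genes were above 0 in only the counts or only the FPKM, which argues against the same reads scaled differently. At most 3.65% of genes had the same read number in another library, which argues against a repeat of another of the 12. RNA of another embryo in the FPKM column may explain the W-linked share of 0.0986%. Which column belongs to the label stays open, and no biological explanation was tested.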

How the results depend on the processing

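Chosen after the results were seen were the offsets, the libraries below a W-linked share of 0.05% (the W cut), chromosome 16 left out and the reads recovered from FPKM; the other alternatives were planned and all were run. Where a value moved, the cause was not tested.

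The 7 hypothalamus genes became 187 with DESeq2, 52 with no count filter, 13 without Z and W genes, 3 with the W covariate, 13 at adjusted p below 0.1, 83 in 1 fit of all libraries, 1 without chromosome 16, and 0 with limma on FPKM (3 settings; 1218, 1201 and 1763 at unadjusted p below 0.05), without libraries above the W cut (914 at unadjusted p below 0.05) and with recovered reads (1423). Leaving out 1 library gave 0 to 39: 0 without each control or treated library 3, 4 without treated library 2, 39 without treated library 1. HSPA2 passed in 14 of 24 alternatives, with log2 fold changes of 1.126 to 1.396 and edgeR, DESeq2 or limma adjusted p from 5.45e-15 to 0.34. HSPB9 passed in 11 (1.124 to 1.365), B3GNT3 in 10 (1.372 to 2.581) and HSP90AB1 in 9 (−1.661 to −1.283).

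A log2 fold change of at least 1 kept 797 genes in whole brain, 1030 for the interaction and 1860 between tissues. With limma on FPKM the interaction had 2434, 2245 and 1055 genes, and the tissues 3684 and 3543 in 2 of 3 settings; over the mean of control and treated libraries the tissues differed at 9743. Leaving out 1 library gave 5473 to 6610 in whole brain, 2340 to 4195 for the interaction and 4200 to 6298 between tissues. Genes shared by the tissues numbered 8 at adjusted p below 0.1 and 6 without Z and W genes.

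Lists past the threshold fell to 0 with an estimated correlation in hypothalamus, whole brain and interaction, and to 4 between tissues; fry gave 0 in hypothalamus, 25 in whole brain, 6 for the interaction and 32 between tissues. Leaving out 1 library gave 6 to 15 (15 without treated library 1), 5 to 11 (5 without treated library 1), 3 to 9 and 13 to 20 in the same order.

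Replicate numbers did not pair the libraries: correlations of same-numbered libraries, after group means were removed, ran from −0.355 to 0.171. With the replicate block edgeR called 2 genes in hypothalamus, 0 higher and 2 lower where the unblocked fit had 6 and 1, and 1 of the 7 calls was kept (HSP90AB1, adjusted p = 0.0374); HSPA2 (0.0886), HSPB9 (0.117) and B3GNT3 (0.143) lost the call. The block gave 6190 in whole brain, 2974 for the interaction and 4938 between tissues, and camera 9, 10, 6 and 19 lists; TRH turned to −0.01861.

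Signs turned only for genes that did not pass. In hypothalamus TRH was −0.08902 with the W covariate, −0.1099 with unfiltered limma, −0.4855 without libraries above the W cut, −0.3792 with recovered reads, −0.01425 with offsets, −0.3097 without control 1 and −0.5391 (lowest) to 0.408 with 1 library left out. BDNF was −0.009925 with limma on log2(FPKM + 1), filtered or not, −0.02165 on log2(FPKM + 0.1), −0.01757 with recovered reads, −0.01172 without treated 3 and −0.08566 to 0.1677 with 1 library left out. HSPA5 was −0.04122 without libraries above the W cut, −0.01754 with offsets and −0.03122 to 0.07719 with 1 library left out. FOS was 0.1303 without libraries above the W cut, 0.01542 without control 3 and −0.2971 to 0.0156 with 1 library left out. In whole brain DIO2 was −0.01441 with the W covariate, −0.02376 without libraries above the W cut (that is, without treated 1) and −0.05325 to 0.16 with 1 library left out. FKBP5 was 0.284 with offsets and −0.1678 to 0.04571 with 1 library left out, MBP −0.08452 with offsets, and POMC 0.1559 without treated 2 and −0.7259 to 0.2286 with 1 library left out. Over all alternatives of named genes, sign and call were unchanged in 770 hypothalamus, 1215 whole brain, 406 interaction and 983 tissue values. The call was lost in 85, 27, 19 and 19 and gained in 55, 2, 0 and 0. At the alternative threshold of adjusted p below 0.1, a call meant passing that threshold. These counts do not compare the size of the fold change, which could move while the call was kept. LIN28A in whole brain, for example, ran from −5.919 to −0.6112 and kept the call in 21 of 21.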

Other observations

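In the mitochondrial genome of the whole brain, ND6, the only protein gene on the minus strand, differed by 2.02 ± 0.18 on the log2 scale, beyond the 12 plus-strand genes at 0.174 to 0.777. In the libraries labelled hypothalamus ND6 did not pass, at −0.25 (edgeR adjusted p = 0.506).

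The chromosome 16 row without a gene name, from 1639025 to 1642068, measured 484.9, 389.7 and 886.9 CPM in whole brain controls. In treated whole brain libraries it measured 10.17, 4.234 and 1.522 CPM. No library labelled hypothalamus exceeded 0.2251 CPM.

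On chromosome 34, 76.6% of 158 protein-coding genes were lower in treated whole brain with a median of −0.652, and on chromosome 2 36.3% were higher with a median of 0.212.

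The serotonin gene TPH2 ran from 4.351 to 81.42 CPM over the 3 treated libraries labelled hypothalamus. Whether the dissections differed in their share of serotonin neurons was not tested.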
